A study of Mus musculus with 14 samples.

How the data were processed

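RNA sequencing was used to measure gene expression in LSK cells, the Lineage−, Sca1+, cKit+ fraction of mouse bone marrow that holds haematopoietic stem and multipotent progenitor cells, sorted by flow cytometry. The 14 libraries fall into 4 groups by sex and by genotype at Lxn, the gene of the carboxypeptidase inhibitor latexin. There were 4 female wild-type, 4 female Lxn knockout, 3 male wild-type and 3 male Lxn knockout libraries. Group and replicate number came from the sample titles. Per the labels' protocols, libraries were made with the NEBNext Ultra II Directional kit and 9 cycles of PCR. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The labels name no sequencing run or date.

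The authors deposited 1 gene table per library, with RSEM expected counts (reads assigned to each gene, with fractions where a read fits more than 1 gene), TPM values and effective lengths for 53465 genes. The deposited expected counts are not normalized, whereas the deposited TPM values are scaled to each gene's effective length and to a fixed sum per library. The effective lengths lay a median of 49 bases under the transcript lengths. The submitters' processing notes name Trim Galore, RSEM and the GRCm38 build. The versions, the aligner, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene on the opposite strand cannot be told apart. Near-identical gene copies share reads that RSEM divides by estimate, and values of such genes are named as uncertain where they are given. Gene symbols and coordinates were taken from GENCODE release M21 (GRCm38) by Ensembl gene identifier, which matched for 53360 of the identifiers and not for 105, and positions are counted from 1.

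The total of expected counts per library ran from 16820670 to 31085824. No pair of libraries in a group agreed within sampling noise, so each was counted as 1 replicate. Where every library of a group had 0 counts of a gene, the ratio was taken against 3 counts over the whole group and is a lower bound. With 1 to 3 counts it is given with an exact conditional 95% interval. Intervals and lower bounds cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

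Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16831 genes. Library sizes were scaled by TMM, and levels are given as CPM, counts relative to the scaled library size as edgeR's cpm gives them, as mean ± SD over the libraries of a group. One quasi-likelihood model with a coefficient per group was fitted to all 14 libraries (10 residual degrees of freedom), with R 4.3.3 and edgeR 4.0.16, and the biological coefficient of variation was 0.14. Tests were two-sided, p-values were adjusted over genes by the Benjamini-Hochberg method and called at 0.05. All adjusted p-values are from edgeR unless another tool is named. The contrasts were knockout against wild type within each sex, the difference between those contrasts (males less females), and males against females within each genotype. Standard errors (SE) of log2 fold changes are given in the same unit.

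A set of 43 gene lists was written from general knowledge, covering programmes of stem and progenitor cells, mature blood cell types that a sort could carry over, cell cycle, stress, metabolism and sex-linked genes. The 42 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was run again with the correlation estimated from the data, and fry from limma 3.58.1 was run as an alternative. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. The rule for the genes named in the text took Lxn, Thbs1, Huwe1 and Mir98, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and libraries that did not overlap between the groups, up to 4 members of each list with the smallest adjusted p, and, between sexes, 9 sex chromosome genes. Where fewer than 10 genes passed in a comparison, the rule took the 10 with the smallest p. Full values are given for a part of them. The grouping, the tests, the lists, the rule and the alternatives described as planned were fixed before the data were examined.

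The alternatives were DESeq2 1.42.0, other scaling factors (RLE and upper quartile), no filter or a stricter filter on low counts, offsets from the RSEM effective lengths, autosomal protein-coding genes only, limma on log2(TPM + 1) and log2(TPM + 0.1), limma-voom with sample weights, a fit to the compared groups alone, the replicate number as a block, and leaving out each library in turn. Leaving out female wild-type libraries 3 and 4 together, summing the pairs of female libraries that resembled each other, the robust form of the edgeR fit and offsets for GC content and gene length were alternatives chosen after seeing the data, as was leaving out each library for the correlation between the sexes. The code was tested on simulated data with known answers. In simulated counts for the 16831 genes, the female knockout contrast recovered 71.6% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 97% of those changed by 2. For the male knockout contrast these shares were 44.8%, 82.1% and 97%, for the difference between the knockout effects 40.3%, 76.1% and 89.4%, for wild-type males against females 55.2%, 77.6% and 100%, and for knockout males against females 55.2%, 86.6% and 97%. Of the calls in these 5 simulations, 2.7% to 7.98% were false. The changed genes all had a mean above 1 CPM, the spread of each gene followed the fitted trend, and the libraries were independent. The likeness of female libraries in pairs was not simulated, so these shares may be too favourable for the real data. No deposited table was left out. Mir98 was not tested because it had 0 counts in all libraries.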

Results

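Gene expression was measured by RNA sequencing of LSK cells, the bone marrow fraction that holds haematopoietic stem cells and early progenitors, from mice with and without a knockout of Lxn. The design crossed sex with genotype, with 4 libraries each of female wild types and female knockouts and 3 each of male wild types and male knockouts. The series title names sex dependence, the microRNA miR-98-3p and thrombospondin 1. Total expected counts were 27545929 to 31085824 in female wild types, 16820670 to 22650793 in female knockouts, 19570140 to 25547303 in male wild types and 17638136 to 21943556 in male knockouts. The first principal component held 37.1% of the variance and separated the sexes. Genes of ribosomal RNA took 0.297% to 0.609% of the counts of female libraries and 0.0428% to 0.0755% of those of male libraries.

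Lxn (3:67457998-67463926, GRCm38), the gene of the carboxypeptidase inhibitor latexin, was lower in knockout than in wild-type libraries of both sexes, but the counts assigned to it did not disappear. Its counts were 439, 483, 365 and 376 in female wild types, 230, 179, 213 and 141 in female knockouts, 550, 442 and 357 in male wild types, and 214, 220 and 207 in male knockouts. Its level was 14.65 ± 2.67 CPM (SD, n = 4) in female wild types and 9.27 ± 1.09 CPM (n = 4) in female knockouts, a log2 fold change of -0.66 (SE 0.13, edgeR adjusted p = 0.0597). In males it was 19.97 ± 1.27 CPM (n = 3) and 11.15 ± 1.14 CPM (n = 3), a log2 fold change of -0.84 (SE 0.15, edgeR adjusted p = 0.0507). All 4 female and all 3 male knockout libraries lay below each wild-type library of their sex. Neither contrast passed the threshold with edgeR, and the adjusted p of the alternatives ran from 0.00128 to 0.217 in females and from 0.000208 to 0.270 in males, with DESeq2 lowest in both. The female contrast also passed with edgeR without female wild-type library 4 (adjusted p = 0.0252) and without libraries 3 and 4 (adjusted p = 0.00665). The knockout effects did not differ between the sexes (difference of -0.19, SE 0.19, adjusted p = 0.809). Which part of Lxn the knockout allele lacks is not given in the sources used here. With the strand setting unknown, any reads of a gene on the opposite strand would be counted here too. The counts left in knockouts therefore do not show how much Lxn transcript remained.

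Thbs1 (2:118111876-118127133), the gene of the matrix glycoprotein thrombospondin 1, differed between male and female libraries and not detectably between genotypes. A difference in preparation or sequencing run cannot be told apart from sex here. The lowest ribosomal RNA share of a female library was 3.931 times the highest of a male library. Between wild types 25.6% of all tested genes passed. Thbs1 was at 44.6 ± 34.2 CPM (n = 4) in female wild types, 40.6 ± 26.9 (n = 4) in female knockouts, 3.66 ± 1.45 (n = 3) in male wild types and 3.50 ± 0.34 (n = 3) in male knockouts. The log2 fold change between male and female wild types was -3.63 (SE 0.63, edgeR adjusted p = 0.000925), and between male and female knockouts it was -3.52 (SE 0.65, edgeR adjusted p = 0.00127). Female wild-type libraries 1 to 4 were at 18.8, 20.4, 91.9 and 47.2 CPM, and the wild-type contrast was -3.001 without library 3 (adjusted p = 0.00131) and -2.44 without libraries 3 and 4 (adjusted p = 0.00502). The knockout contrast was -0.15 in females (SE 0.46, adjusted p = 0.939) and -0.04 in males (SE 0.77, adjusted p = 1), and the difference between them was 0.11 (SE 0.90, adjusted p = 0.986). Leaving out 1 library moved the female contrast between -0.70, without female knockout library 4, and 0.48, without female wild-type library 3. Without female wild-type libraries 3 and 4 it was 1.04 (adjusted p = 0.276), so its direction turned. Mir98 (X:151913214-151913321), the precursor gene of the microRNA, had 0 counts in all 14 libraries. Its host gene Huwe1 (X:151800807-151935417), which encodes a ubiquitin ligase, was at 724.8 ± 23.0 CPM in female wild types and 627.4 ± 44.9 CPM in male wild types (log2 fold change -0.21, adjusted p = 0.0168). Huwe1 did not pass between the knockouts of the sexes (-0.16, adjusted p = 0.0519) or with Lxn genotype in females (0.03, adjusted p = 0.894) or males (0.07, adjusted p = 0.969). A library of this kind measures the host transcript and not the mature microRNA.

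**Figure D1:**
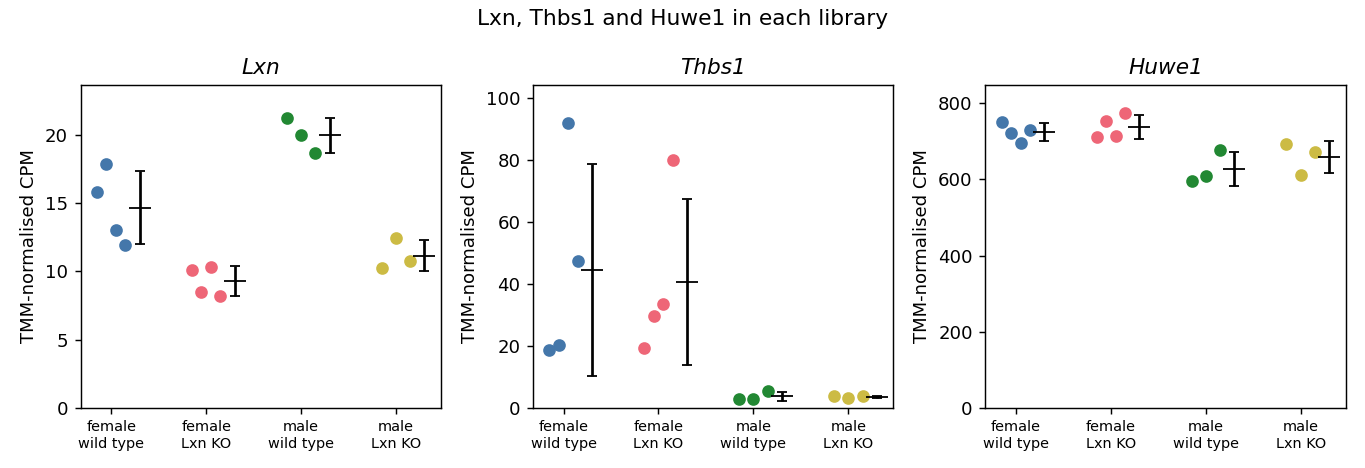
TMM-normalised CPM of Lxn, Thbs1 and Huwe1 on linear axes, with 1 point per library and the mean and SD of each group (n = 4 in females, n = 3 in males). Each knockout library lies below each wild-type library of its sex for Lxn. Thbs1 separates male from female libraries, where preparation or run cannot be told apart from sex.

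The comparison of female knockouts with female wild types asked what differs in female LSK cells labelled as Lxn knockout, in which Lxn was lowered but, with all libraries, not past the threshold. Among single genes, Slc4a1 of red cells, the basophil protease genes Prss34 and Mcpt8, and Cpa3 fell. Slc4a1, which encodes the anion exchanger of the red cell membrane, went from 19.2 ± 13.4 to 0.661 ± 0.327 CPM (log2 fold change -4.82, SE 0.64, adjusted p = 0.00462). The basophil protease genes Prss34 (-2.67, SE 0.45, adjusted p = 0.0255) and Mcpt8 (-1.50, SE 0.25, adjusted p = 0.0255) fell, as did Cpa3 (3:20215620-20242181), the gene of the mast cell carboxypeptidase, from 53.02 ± 3.30 to 36.4 ± 4.09 CPM (-0.54, SE 0.07, adjusted p = 0.00533). In female wild types Cpa3 ran from 48.1 to 55.2 CPM and was lowest in library 3. Prss34 ran from 27.3 to 97.5 CPM there and Mcpt8 from 24.3 to 52.0 CPM. Which cells held the Cpa3 transcripts was not tested. Rac2, the Rho GTPase gene of blood cells that steers adhesion and migration, fell by 0.26 on the log2 scale (SE 0.04, adjusted p = 0.0235). Without female wild-type libraries 3 and 4, Slc4a1 still passed with a smaller fall (-3.49, adjusted p = 0.00842), whereas Prss34 (0.0787), Mcpt8 (0.0708) and Rac2 (0.0833) did not pass.

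In females 24 of 16831 genes passed an adjusted p of 0.05, with 7 higher and 17 lower in knockouts. Of these, 1 rose and 11 fell by at least 2-fold. With the female libraries summed in the pairs that resembled each other (1 with 2 and 3 with 4), 6 genes passed, 0 higher and 6 lower. None of the rises below was called with pairs as units. The libraries of all 24 did not overlap between genotypes. A call selects for such separation, so the 2.86% that chance gives for unselected genes is no reference for these 24. Gm16867 (14:69363504-69503362), a protein-coding gene model on chromosome 14, fell from 1180 counts over the group to 2, a ratio of 421.6 (95% interval 116.5 to 3485, adjusted p = 1.59e-05). Entpd4 (14:69337174-69367270), the nucleotidase gene whose span overlaps it and whose near copy Entpd4b lies in the same region, fell from 52.8 ± 0.91 to 30.8 ± 3.54 CPM (-0.78, SE 0.07, adjusted p = 5.64e-05). Lrmda (14:22019712-23056085), a melanocyte differentiation gene elsewhere on that chromosome, fell from 7.70 ± 0.45 to 0.98 ± 0.39 CPM (-2.99, SE 0.24, adjusted p = 1.88e-05). Gdf3 (6:122605403-122610087), which encodes a ligand of the TGF-beta family, fell by 0.75 on the log2 scale (SE 0.10, adjusted p = 0.00533). Clca3a1 (3:144729677-144760977) of the chloride channel accessory family rose from 16.4 ± 1.33 to 26.4 ± 2.65 CPM (0.69, SE 0.11, adjusted p = 0.0155). The endosome recycling genes Ehd3 (0.65, adjusted p = 0.0383) and Rab4a (0.59, adjusted p = 0.0458), the methyltransferase gene Fam173b (0.45, adjusted p = 0.0419) and Tmem181a (0.42, adjusted p = 0.0299) also rose. The values of Entpd4, of Gm16867 in the same duplicated region and of Tmem181a, a near copy of Tmem181b-ps, are uncertain because reads are shared between copies.

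Gm21887 (X:170009659-170019281, -1.65, adjusted p = 0.0103), Gm47283 (Y:90784738-90816464, -1.58, adjusted p = 0.00534) and Gm10800 (2:98666547-98667301, -1.30, adjusted p = 0.00576) fell too. Gm47283 and Gm21887 lie at the ends of the sex chromosomes with near-identical copies, so their values are uncertain. The other 7 called genes fell outside the naming rule and were chosen after their values were seen. They were Tcf7, a T-lineage transcription factor gene (-1.35, adjusted p = 0.0255), the kinase gene Lrrk2 (-0.54, adjusted p = 0.00576), Entpd4b (-0.61, adjusted p = 0.00576), Gm27177 (-2.98, adjusted p = 0.00203), Mid1-ps1 (at least 26.2-fold lower), Tmem181b-ps (0.82, adjusted p = 8.18e-05) and Gm47601 (3.01, adjusted p = 0.00534). Entpd4b and Tmem181b-ps are near copies of other genes, Gm27177 is antisense and Gm47601 lies inside Lrmda, so these values are uncertain. Mid1-ps1 is annotated beside Gm47283 at the end of the Y chromosome (Y:90753057-90763485). Female wild types held 110 counts of it over the group, as they held counts of Gm47283, and its value is uncertain too. Of the 17 calls under the rule, 8 remained without any single library (Cpa3, Entpd4, Gdf3, Gm10800, Gm16867, Gm47283, Lrmda and Slc4a1), and the count fell to 14 without female knockout library 4. Each of the other 9 had its highest adjusted p without that library, with Clca3a1 at 0.0921, Ehd3 at 0.134, Fam173b at 0.175, Gm21887 at 0.0584, Mcpt8 at 0.134, Prss34 at 0.134, Rab4a at 0.187, Rac2 at 0.129 and Tmem181a at 0.134. Each of the other 7 libraries also ended at least 1 of these calls when left out. Without female wild-type libraries 3 and 4 together it rose to 101 genes, 19 of them shared, but Ehd3 (adjusted p = 0.106), Rab4a (0.113), Mcpt8 (0.0708), Prss34 (0.0787) and Rac2 (0.0833) were then past the threshold no longer.

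**Figure D2:**
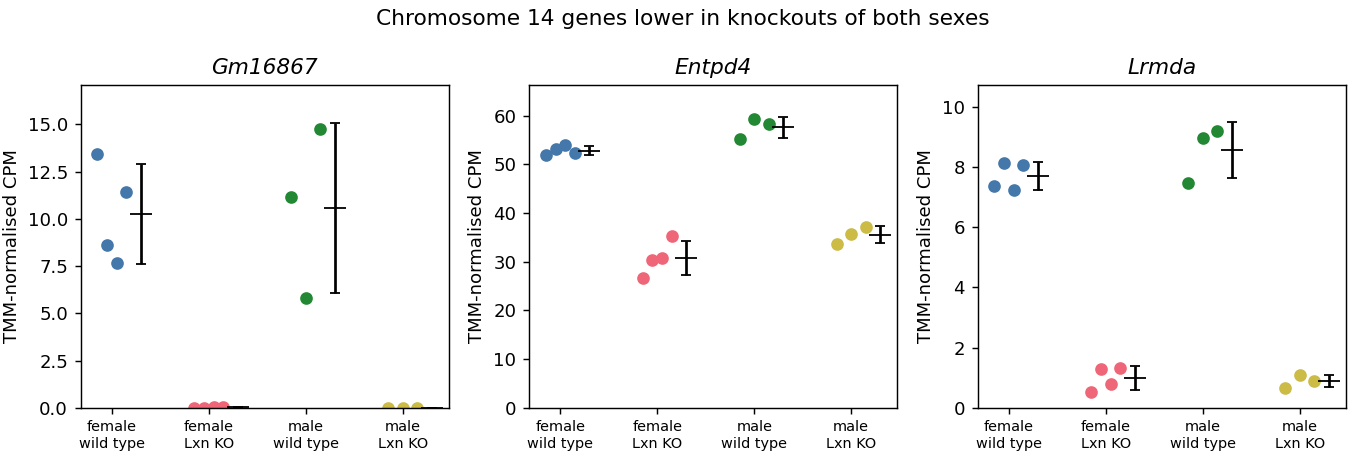
TMM-normalised CPM of Gm16867, Entpd4 and Lrmda on linear axes, with 1 point per library and the mean and SD of each group (n = 4 in females, n = 3 in males). Each knockout library lies below each wild-type library of its sex for the 3 genes.

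Among gene lists in females, interferon response and stem cell identity rose and immediate-early genes and histones fell with camera's preset correlation, and none of these 4 held with an estimated one. With camera 25 of 42 lists passed, 7 up and 18 down, of which 2 held with an estimated correlation (T and NK cell markers, and migration and Rho signalling), and fry called 9. The interferon response list rose, with positive fold changes in 29 of 30 genes, with a median log2 fold change of 0.22 (camera adjusted p = 5.00e-14, and adjusted p = 0.104 with an estimated correlation). None of its genes passed over all genes and 13 passed when adjusted over the list alone. The list of stem cell identity rose, with positive fold changes in 28 of 29 genes, with a median of 0.23 (camera adjusted p = 8.33e-11, and adjusted p = 0.147 with an estimated correlation), and 5 passed when adjusted over the list alone. Its members Mllt3 (0.35, adjusted p = 0.0802) and Fgd5 (0.63, adjusted p = 0.124), which mark stem cells and were chosen after their values were seen, did not pass over all genes. The genes of aged stem cells had a median of 0.32 (camera adjusted p = 6.25e-08, and adjusted p = 0.119 with an estimated correlation), with Clca3a1 past over all genes and 3 adjusted over the list alone. The fetal and imprinted genes, with a median of 0.38 and 2 of 15 past adjusted over the list alone, rose too (camera adjusted p = 1.98e-06, and adjusted p = 0.0877 with an estimated correlation). Cholesterol synthesis rose, positive in 20 of 21 genes with a median of 0.22 (2.83e-09, and adjusted p = 0.147 with an estimated correlation). The G2 and M phase genes rose as well, positive in 29 of 30 with a median of 0.08 (9.65e-08, and adjusted p = 0.273 with an estimated correlation). Megakaryocyte and erythroid priming rose with a median of 0.17 (0.000107, and adjusted p = 0.253 with an estimated correlation). Of the priming list, 9 genes rose and 3 fell adjusted over the list alone, and the mean was 0.00112.

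The immediate-early genes, which respond to stress and handling, fell, with negative fold changes in 23 of 25 members with a median of -0.74 (camera adjusted p = 1.26e-14, and adjusted p = 0.147 with an estimated correlation). None passed over all genes and 17 fell when adjusted over the list alone. Replication-dependent histones fell, with negative fold changes in 33 of 34 genes (median -0.58, 5.92e-11, and adjusted p = 0.104 with an estimated correlation), and the S phase genes had negative fold changes in 28 of 30 (median -0.11, 7.82e-08, and adjusted p = 0.244 with an estimated correlation). In both lists 0 genes passed over all genes or adjusted over the list alone. T and NK cell markers fell, with negative fold changes in 11 of 12 genes (median -0.50, 1.85e-07, and adjusted p = 0.0440 with an estimated correlation), with a median of -0.50 also when Trbc2, which had 0 counts in knockouts, is put at its bound of at least 9.77-fold. Migration and Rho signalling fell, with negative fold changes in 16 of 18 genes (median -0.12, 7.35e-07, and adjusted p = 0.0440 with an estimated correlation), with Rac2 past over all genes and 9 adjusted over the list alone. The list of mast cell, basophil and eosinophil genes had Cpa3, Mcpt8 and Prss34 past over all genes and 8 adjusted over the list alone (median -0.35, 7.63e-07, and adjusted p = 0.0877 with an estimated correlation). Lymphoid priming (median -0.21, 1.78e-06, and adjusted p = 0.104 with an estimated correlation), NF-kB targets (median -0.17, 0.000141, and adjusted p = 0.119 with an estimated correlation) and quiescence genes (median -0.13, 0.000179, and adjusted p = 0.111 with an estimated correlation) fell as well. Ribosomal proteins fell, with negative fold changes in 45 of 47 genes and a median of -0.07 (3.85e-05, and adjusted p = 0.470 with an estimated correlation). Of these 0 passed over all genes or adjusted over the list alone.

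Neutrophil markers, granule and calprotectin genes that a stem cell sort should leave behind, fell, with negative fold changes in 17 of 17 genes in female knockouts with a median of -3.95 (camera adjusted p = 1.32e-12, and adjusted p = 0.147 with an estimated correlation), and 16 passed adjusted over the list alone. S100a8, chosen after its values were seen, stood at 298 and 316 CPM in female wild-type libraries 3 and 4, at 8.35 and 15.6 CPM in libraries 1 and 2 and at 0.678 to 40.9 CPM in female knockouts (log2 fold change -3.54, adjusted p = 0.248). Erythroid markers had a median of -0.62 (2.28e-07, and adjusted p = 0.158 with an estimated correlation), with Slc4a1 past over all genes and 9 down and 1 up adjusted over the list alone, and a median of -0.10 without female wild-type libraries 3 and 4. Dendritic cell markers (median -0.25, 1.01e-06, and adjusted p = 0.147 with an estimated correlation), B cell markers (median -0.75, 6.18e-05, and adjusted p = 0.235 with an estimated correlation), myeloid priming (median -0.18, 0.000881, and adjusted p = 0.450 with an estimated correlation) and genes of the sort gate (median -0.12, 0.0126, and adjusted p = 0.104 with an estimated correlation) fell too. Without female wild-type libraries 3 and 4, these calls ended for neutrophil (camera adjusted p = 0.226), dendritic cell (0.143), B cell (0.908), myeloid (0.341) and gate genes (0.259). B cell markers were also past it no longer without female wild-type library 3 alone (0.0588), and myeloid priming without female knockout library 3 (0.0849) or 4 (0.0855). Mitochondrially encoded genes (median -0.09, 0.00816, and adjusted p = 0.431 with an estimated correlation) did not pass without female wild-type library 1 (0.0965) or 2 (0.0939) or female knockout library 3 (0.0541) or 4 (0.0889). Oxidative phosphorylation (median -0.04, and 0.01 with limma on TPM, 0.0327, and adjusted p = 0.734 with an estimated correlation) did not pass without female wild-type library 1 (0.468) or 2 (0.460) or female knockout library 2 (0.164), 3 (0.0662) or 4 (0.0507). Thrombospondin receptors (camera adjusted p = 0.448), the TGF-beta list (0.357) and the neighbours of Lxn (0.304, but 0.0139 without female wild-type libraries 3 and 4) did not pass. That alternative also brought monocyte and macrophage markers (from 0.919 to 0.00156) and, each to 0.0482, the let-7, p53 and ribosome biogenesis lists past the threshold. Adhesion and matrix genes passed without female wild-type library 2 (0.0459), and X-linked haematopoietic genes without female wild-type library 4 (0.0463) or female knockout library 2 (0.0228).

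**Figure D3:**
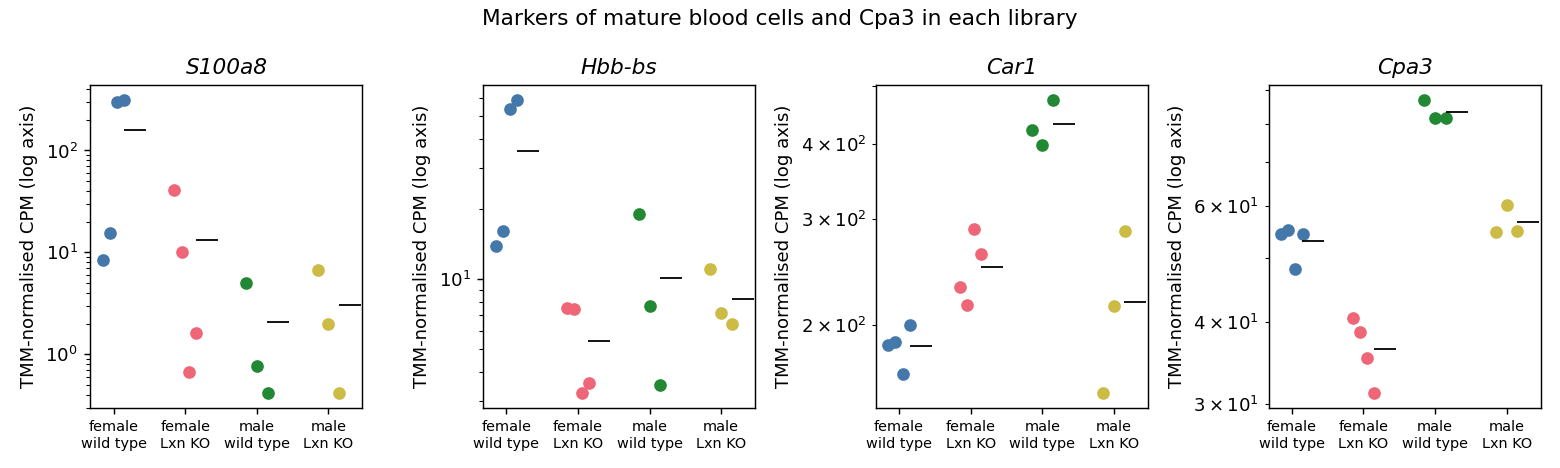
TMM-normalised CPM of S100a8, Hbb-bs, Car1 and Cpa3 on log axes, with 1 point per library and a bar at the mean of each group (n = 4 in females, n = 3 in males). S100a8 and Hbb-bs are highest in female wild-type libraries 3 and 4, Car1 is lower in male knockouts (the difference between the sexes did not pass, adjusted p = 0.0666), and Cpa3 is lower in the knockouts of both sexes.

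The comparison of male knockouts with male wild types asked the same of male LSK cells. Car1 of the red cell lineage and the carboxypeptidase gene Cpa3 fell. Car1 (3:14766216-14808368), the gene of a carbonic anhydrase of the red cell lineage, fell from 431.5 ± 38.9 to 218.9 ± 66.5 CPM (log2 fold change -0.98, SE 0.16, adjusted p = 0.0423), whereas its female values were 184.8 and 249.6 CPM (0.43, adjusted p = 0.253). Cpa3 fell from 83.4 ± 3.14 to 56.6 ± 3.04 CPM (-0.56, SE 0.08, adjusted p = 0.0163). Scin (12:40059769-40134228), which encodes an actin-severing protein of blood cells, fell from 11.95 ± 0.52 to 6.03 ± 0.69 CPM (-0.99, SE 0.14, adjusted p = 0.0123). Nnt (13:119335448-119408997), the gene of the mitochondrial transhydrogenase that is partly deleted in C57BL/6J mice, rose from 55.5 ± 1.05 to 101.4 ± 8.64 CPM (0.87, SE 0.12, adjusted p = 0.0123).

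In males 11 genes passed, of which 1 rose and 10 fell, and 3 of them changed at least 2-fold. All 11 had libraries that did not overlap between genotypes, for which the call itself selects. Among unselected genes chance gives 10%, which is no reference for called ones. Gm16867 fell from 699 counts over the group to 0 and was at least 200.7-fold lower (adjusted p = 4.82e-05). Lrmda fell from 8.55 ± 0.93 to 0.876 ± 0.20 CPM (-3.29, SE 0.28, adjusted p = 4.82e-05), Entpd4 from 57.6 ± 2.17 to 35.5 ± 1.75 CPM (-0.70, SE 0.08, adjusted p = 0.00168), and Gdf3 by 0.94 on the log2 scale (SE 0.13, adjusted p = 0.00752). AC149090.1 (JH584304.1:52190-59690), a gene on an unplaced scaffold whose copies make its value uncertain, fell by 0.77 (SE 0.10, adjusted p = 0.00419), and its female value was -0.44 (adjusted p = 0.0534). The glutathione transferase gene Gstm5 fell (-0.68, SE 0.10, adjusted p = 0.0188). Gm27177, antisense and chosen after its values were seen, fell as well (-2.56, adjusted p = 0.0381). Of the 10 calls under the rule, AC149090.1, Entpd4, Gm16867 and Lrmda remained without any single library. The values of Entpd4 and Gm16867 are uncertain for the copies named above. The others had their highest adjusted p without male wild-type library 1 (Cpa3 0.131, Gstm5 0.131, Nnt 0.107 and Scin 0.107), male wild-type library 3 (Car1 0.251) or male knockout library 1 (Gdf3 0.0750). Each of the 6 libraries ended at least 1 of these calls when left out. The count was 5 without male wild-type library 1, 4 without male wild-type library 3, 4 without male knockout library 1 and 25 without male knockout library 3.

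With camera 8 of 42 lists passed in males, 4 up and 4 down, and 0 held with an estimated correlation or passed with fry. Erythroid markers fell, with negative fold changes in 17 of 17 genes with a median of -0.61 (camera adjusted p = 1.26e-17, and adjusted p = 0.140 with an estimated correlation), with Car1 past over all genes and 10 adjusted over the list alone. Megakaryocyte and erythroid priming fell, with negative fold changes in 21 of 24 genes (median -0.15, 1.97e-11, and adjusted p = 0.144 with an estimated correlation), with 7 down and 1 up adjusted over the list alone. Mast cell, basophil and eosinophil genes had a median of -0.25 (1.10e-06, and adjusted p = 0.140 with an estimated correlation), with Cpa3 past over all genes and 4 adjusted over the list alone. Myeloid priming rose, with positive fold changes in 19 of 20 genes (median 0.36, 2.76e-06, and adjusted p = 0.890 with an estimated correlation), but not past the threshold without male knockout library 1 (0.157). The interferon response list (median 0.15, 0.00348, and adjusted p = 0.890 with an estimated correlation) lost its call without male knockout library 1 (0.0973) or 2 (0.0809), and ribosomal proteins (median -0.05, 0.00128, and adjusted p = 0.9498 with an estimated correlation) without male knockout library 3 (0.440). Glycolysis (median 0.10, and -0.02 with limma-voom, 0.0150, and adjusted p = 0.890 with an estimated correlation) did so without male wild-type library 3 (0.166) or male knockout library 1 (0.672). Gate genes (median 0.14, 0.0192, and adjusted p = 0.144 with an estimated correlation) did so without male wild-type library 2 (0.0508) or 3 (0.104) or male knockout library 2 (0.104) or 3 (0.0629). The heat shock list, at 0.123, came to 0.000156 without male wild-type library 1 and to 2.89e-23 without male knockout library 1. Other lists that did not pass in all libraries passed when 1 male library was left out. These were G2 and M phase (0.00288 without wild-type library 2, 1.79e-05 without wild-type 3 and 0.0233 without knockout 3), immediate-early genes (0.0229 without wild-type 1 and 0.000172 without knockout 3) and cholesterol synthesis (0.00179 without wild-type 3). S phase (0.00967 without knockout 2), aged stem cells (0.0128 without knockout 3), oxidative phosphorylation (7.46e-06 without knockout 1 and 0.0461 without knockout 3) and ribosome biogenesis (9.8e-08 without knockout 1 and 0.00446 without knockout 2) did so too.

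The series title asks whether the knockout acts differently in the sexes, and 6 genes fell in both. They were Cpa3, Entpd4, Gdf3, Gm16867, Gm27177 and Lrmda, and 0 genes rose in both. For independent lists of separate genes the expected number of shared falls is 0.0101. Entpd4, Gm16867 and Gm27177 are not separate, since they lie in the same region, where near copies can share reads. The 0.0101 therefore does not measure how unusual the 6 shared falls are. A strain or copy-number difference between the stocks could also give falls in both sexes and was not told apart from genotype. Of the 29 genes called in either sex, a choice that favours shared signs, 22 had the same sign in both. Across all 16831 genes, which are not independent replicates, the knockout fold changes of the sexes had a Pearson r of 0.0461 and a Spearman rho of -0.0888, and 45.9% of genes had the same sign. Over genes with a mean of at least 10 CPM r was -0.137.

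**Figure D4:**
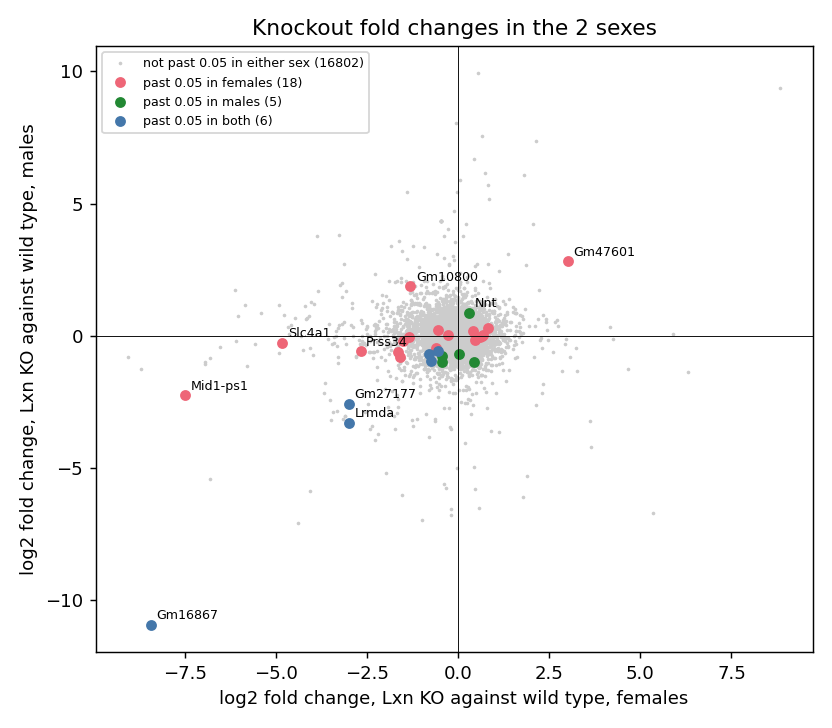
Log2 fold changes of Lxn knockout against wild type in females (horizontal axis) and males (vertical axis), with 1 point per tested gene and colours for the 29 genes past an adjusted p of 0.05. The 6 genes past it in both sexes fell in both.

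The difference between the knockout effects, the direct test of sex dependence, left 0 of 16831 genes past an adjusted p of 0.05 with edgeR. At an unadjusted p under 0.05 there were 1728 genes, the smallest adjusted p was 0.0666, and DESeq2 called 158. The smallest p-values belonged to Trib2, a pseudokinase gene (difference of -1.34, SE 0.20, adjusted p = 0.0666), Car1 (-1.41, SE 0.22, adjusted p = 0.0666) and Lrrk2 (0.78, SE 0.12, adjusted p = 0.0666). Trib2 was at 22.5 CPM in female wild types, 30.6 in female knockouts, 27.5 in male wild types and 14.8 in male knockouts. Casp3 (-0.54), Optn (-0.87), Grb10 (-0.69), Zfpm1 (-0.62), Midn (0.41), Ptpn14 (-1.14) and A730089K16Rik (-1.57) followed, each at an adjusted p of 0.0978. The count was 23 without male knockout library 3, 2 without male knockout library 1 and 1 without male knockout library 2.

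For gene lists, 22 of 42 differed between the knockout effects with camera, 14 up and 8 down, whereas 0 held with an estimated correlation and fry called 2 (gate genes, 0.0130, and migration and Rho signalling, 0.0192). Megakaryocyte and erythroid priming had a median difference of -0.39 (camera adjusted p = 3.37e-12, and adjusted p = 0.154 with an estimated correlation), with a median of 0.17 in females and -0.15 in males. Immediate-early genes (0.91, 1.20e-10, and adjusted p = 0.303 with an estimated correlation), histones (0.74, 6.17e-08, and adjusted p = 0.195 with an estimated correlation) and myeloid priming (0.69, 5.68e-08, and adjusted p = 0.303 with an estimated correlation) had positive medians. In female knockouts the 3 lists passed as lower with camera's preset correlation but not with an estimated one. The female call of myeloid priming also ended without female wild-type libraries 3 and 4 (camera adjusted p = 0.341). Stem cell identity (-0.31, 1.68e-06, and adjusted p = 0.304 with an estimated correlation), cholesterol synthesis (-0.27, 1.95e-06, and adjusted p = 0.303 with an estimated correlation) and genes of aged stem cells (-0.40, 1.08e-05, and adjusted p = 0.303 with an estimated correlation) had negative medians. These 3 lists passed as higher in female knockouts with camera's preset correlation, but not with an estimated one. Neutrophil markers differed by a median of 4.29 (5.17e-09, and adjusted p = 0.303 with an estimated correlation), but at 0.118 without female wild-type libraries 3 and 4. Leaving those libraries out brought ribosomal proteins (0.000174), oxidative phosphorylation (0.000199), erythroid markers (0.0018), monocyte and macrophage markers (0.00843), quiescence (0.00946) and mitochondrially encoded genes (0.0146) past the threshold. Lists that did not pass in all libraries but passed without some 1 library were erythroid markers (lowest 0.000855, without male knockout 3), oxidative phosphorylation (0.00235, without male knockout 3), ribosome biogenesis (7.35e-06, without male knockout 1), quiescence (0.0137, without male wild-type 1) and carboxypeptidases (0.0451, without female wild-type 4).

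Males and females of the wild type were compared to describe how LSK libraries of the sexes differ without the knockout. Preparation or run cannot be told apart from sex here, since the ribosomal RNA shares of the sexes did not overlap. Pgr (9:8899833-8968611), the progesterone receptor gene, was at 34.4 ± 4.31 CPM in females and 2.31 ± 0.65 CPM in males (log2 fold change -3.92, SE 0.27, adjusted p = 2.21e-07). Selp, the P-selectin gene (-1.54, SE 0.13, adjusted p = 2.24e-06), Cd47, the gene of a thrombospondin receptor (-0.76, SE 0.06, adjusted p = 8.43e-07), and the stem cell transcription factor genes Fli1 (-0.64, adjusted p = 1.08e-06) and Meis1 (-0.53, adjusted p = 0.000438) were higher in females. The lists of stem cell identity (camera adjusted p = 0.936) and stem cell transcription factors (0.454) did not pass. Flt3, the receptor gene of multipotent progenitors (0.52, SE 0.07, adjusted p = 0.00018), and Dntt, the gene of the nucleotide-adding enzyme of lymphoid cells (0.96, SE 0.14, adjusted p = 0.000262), were higher in males.

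Between wild types 4311 genes passed, 25.6% of those tested, with 2116 higher in males and 2195 higher in females. Of these, 1018 differed at least 2-fold (222 and 796), and 4004 had libraries that did not overlap. This count is no separate evidence, since a call selects for such separation and the 5.71% given by chance holds for unselected genes. With limma on log2(TPM + 1), where the median of all genes lay at -0.101, the split was 813 to 2935. The count was 2600 without male wild-type library 2. Xist, the X inactivation transcript, was at 2718 ± 256 CPM in females and 0.593 ± 0.229 CPM in males (-12.11, SE 0.21, adjusted p = 1.15e-14). Kdm6a (-0.78), Eif2s3x (-0.84), Kdm5c (-0.53) and Ddx3x (-0.40), which escape X inactivation, were higher in females, at adjusted p from 4.99e-07 to 0.000974. Of their Y-linked partners, Eif2s3y was 9157-fold higher in males (95% interval 1643 to 361700), and Ddx3y (11.29), Kdm5d (9.36) and Uty (9.34) also passed. Fam25c (14:34351881-34355433) and Dsg1a (18:20310811-20343350), the gene of a skin desmoglein, were at least 755-fold and at least 622.1-fold higher in males, and Klkb1, a protease gene of the liver, was higher too (6.47, SE 0.31, adjusted p = 3.13e-09). Gm10800, which had 1 to 3 counts over the male group, was 894.2-fold higher in females (95% interval 160.3 to 35340). The neutrophil genes Ngp (-7.59, adjusted p = 0.00602) and Ltf (-8.48, adjusted p = 0.00711) were higher in females, where libraries 3 and 4 held most of their counts.

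Of the lists, 11 passed camera between wild types, 8 higher in males and 3 higher in females, 2 held with an estimated correlation and 16 passed with fry. Y-linked genes (camera adjusted p = 8.84e-258, and adjusted p = 1.60e-08 with an estimated correlation) and genes that escape X inactivation (3.14e-28, and adjusted p = 1.50e-05 with an estimated correlation) separated the sexes, with 10 of 14 escape genes past over all genes and 11 adjusted over the list alone. Ribosomal proteins were higher in males (4.59e-36, and adjusted p = 0.202 with an estimated correlation), with 42 of 47 genes past over all genes, Rpl10a at 306.6 and 524.8 CPM and Rps6 at 0.81 (adjusted p = 3.25e-07) among them. Oxidative phosphorylation was higher in males (4.50e-12, and adjusted p = 0.620 with an estimated correlation) in 32 of 41 genes over all genes and 36 adjusted over the list alone, Ndufa6 (0.64, adjusted p = 3.91e-05) among them. Mitochondrially encoded genes (0.000271, and adjusted p = 0.620 with an estimated correlation) had 8 genes higher, with mt-Nd3 at 0.93, and 2 lower, or 8 and 3 adjusted over the list alone. Cholesterol synthesis (4.19e-05, and adjusted p = 0.620 with an estimated correlation) had 8 of 21 past over all genes and 14 adjusted over the list alone, with Msmo1 at 0.90. Lymphoid priming (0.0146, and adjusted p = 0.620 with an estimated correlation) had 11 genes higher and 3 lower over all genes, and 12 and 3 adjusted over the list alone. Megakaryocyte and erythroid priming (0.0129, and adjusted p = 0.686 with an estimated correlation) had 10 higher and 2 lower, or 11 and 4 adjusted over the list alone, with Car1 at 1.22. Heat shock genes (0.0123, and adjusted p = 0.751 with an estimated correlation) lost the call without male wild-type library 3 (0.0556) or without female wild-type libraries 3 and 4 (0.0794). Neutrophil markers were higher in females (0.000129, and adjusted p = 0.686 with an estimated correlation), as were immediate-early genes (0.0165, and adjusted p = 0.751 with an estimated correlation), the latter not without female wild-type library 1 (0.0689) or 2 (0.174) or male wild-type library 3 (0.0745). Thrombospondin receptors did not pass (0.0587), but came to 0.0248 without female wild-type library 2 and to 0.0366 without male wild-type library 3. Histones did not pass in all libraries (0.0509) but passed without female wild-type library 3 (0.0208), library 4 (0.0109) or both (0.00053), and NF-kB targets went from 0.306 to 0.0183 without both. B cell markers (lowest 0.0164, without female wild-type 1), myeloid priming (0.0157, without male wild-type 2) and adhesion genes (0.0373, without female wild-type 2) did not pass in all libraries but passed without some 1 library.

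The same comparison between knockouts asked which sex differences stand among libraries labelled as Lxn knockout. Flt3 (0.93, SE 0.07, adjusted p = 9.01e-07) and Dntt (1.23, SE 0.14, adjusted p = 2.93e-05) were higher in males. Trbc2, the T cell receptor gene chosen after its values were seen, was at least 37.2-fold higher in males. Clca3a1 (-1.37, SE 0.13, adjusted p = 3.45e-06), the growth factor adaptor gene Grb10 (-1.37, SE 0.09, adjusted p = 1.24e-07) and Pgr (-4.24, SE 0.29, adjusted p = 1.71e-07) were higher in females, and Rac2 was higher in males (0.39, SE 0.05, adjusted p = 4.43e-05).

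Between knockouts 4255 genes passed, 25.3% of those tested, with 2283 higher in males and 1972 higher in females. Of these, 794 differed at least 2-fold (275 and 519), and 3966 had libraries that did not overlap. Again the call selects for such separation, and the 5.71% given by chance holds for unselected genes. With limma on log2(TPM + 1), where the median of all genes lay at -0.131, the split was 853 to 3331, and with upper-quartile factors it was 1884 to 2309. Xist was at 3020 ± 216 CPM in females and 0.9496 ± 0.577 CPM in males (-11.62, adjusted p = 1.34e-14). Kdm6a (-0.77), Eif2s3x (-0.73) and Kdm5c (-0.58) were higher in females and Ddx3x did not pass (-0.11, adjusted p = 0.271). Ddx3y, Eif2s3y and Uty were at least 2719-fold, 2014-fold and 976.6-fold higher in males, and Kdm5d passed at 9.03. Fam25c was at least 744.7-fold and Dsg1a at least 677.8-fold higher in males. Lars2, a leucyl-tRNA synthetase gene, was at 1452 ± 479 CPM in females and 126.5 ± 28.1 CPM in males (-3.52, SE 0.27, adjusted p = 7.04e-07), and Gm10800 was lower in males (-6.18, adjusted p = 4.09e-08). Ribosomal RNA took 0.364% to 0.609% of the counts of female knockout libraries and 0.0573% to 0.0652% of those of male ones. A difference in preparation therefore cannot be told apart from sex for either gene. The heat shock genes Hspa1a (3.57, adjusted p = 0.0127) and Hspa1b (3.29, adjusted p = 0.00989) were higher in males, with 139.9 CPM of Hspa1a in male knockout library 1 and 10.2 CPM in library 3.

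Of the lists, 14 passed camera between knockouts, 9 higher in males and 5 higher in females, 2 held with an estimated correlation and 18 passed with fry. Y-linked genes (2.65e-226, and adjusted p = 6.55e-09 with an estimated correlation) and X escape genes (1.26e-28, and adjusted p = 9.49e-06 with an estimated correlation) separated the sexes. Ribosomal proteins (4.06e-38, and adjusted p = 0.0919 with an estimated correlation) had 42 genes higher in males and 1 lower, or 43 and 1 adjusted over the list alone. Oxidative phosphorylation (5.59e-15, and adjusted p = 0.371 with an estimated correlation) had 35 higher, or 37 adjusted over the list alone, and mitochondrially encoded genes (1.33e-05, and adjusted p = 0.298 with an estimated correlation) 8 higher and 1 lower. Lymphoid priming was higher in males (1.34e-07, and adjusted p = 0.0845 with an estimated correlation) in 15 genes and lower in 1, or 16 and 1 adjusted over the list alone. T and NK cell markers (0.00964, and adjusted p = 0.209 with an estimated correlation) had 6 past and a median of 0.60, also with Trbc2 at its bound. Migration and Rho signalling (0.000336, and adjusted p = 0.0845 with an estimated correlation) had 7 past, or 10 adjusted over the list alone. Genes of aged stem cells were higher in females (5.27e-05, and adjusted p = 0.336 with an estimated correlation), with 9 past. Stem cell identity was higher in females (0.00422, and adjusted p = 0.731 with an estimated correlation), but not past the threshold without male knockout library 1 (0.0534). The S phase genes (median 0.18, and -0.004 with limma on TPM, 0.00964, and adjusted p = 0.846 with an estimated correlation) lost their call without male knockout library 1 (0.138), and so did the fetal and imprinted genes, higher in females (0.0219, and adjusted p = 0.371 with an estimated correlation), at 0.0802. Gate genes were higher in males (median 0.25, and -0.035 with limma on log2(TPM + 1), 0.00964, and adjusted p = 0.0861 with an estimated correlation). The G2 and M phase genes, higher in females (0.0498, and adjusted p = 0.862 with an estimated correlation), lost their call without female knockout library 2 (0.0661) or 3 (0.0715) or male knockout library 3 (0.183). Lists that passed here without some 1 library, but not in all libraries, were heat shock (lowest 0.00623, without male knockout 3), ribosome biogenesis (0.0107, without male knockout 1), megakaryocyte and erythroid priming (0.0159, without male knockout 3), sex hormone receptors and targets (0.0218, without female knockout 1), interferon response (0.0229, without male knockout 1) and immediate-early genes (0.0437, without male knockout 3).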

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

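The tests of library preparation, of a strain or copy-number difference, of chromosome linked to Lxn and of female wild-type libraries 3 and 4 in this part were chosen only after the results were seen. Single libraries stood apart in 11 of 160 groups of 4 values, where chance gives about 1 in 20. In female wild types, Cpa3 was at 48.11 CPM in library 3 against 54.32 to 55.24 in the others. Library 4 was high for Fam173b (20.67 CPM against 16.47 to 16.91) and Trib2 (24.83 against 21.49 to 21.88). Library 2 was high for Rpl10a (341.6 CPM against 290.9 to 297.2), and library 1 was low for Lars2 (797.8 CPM against 1253 to 1320). Library 1 also had the lowest ribosomal RNA share of the female wild types, at 0.2968% against 0.4818% to 0.5354%. Whether Lars2 counts follow that share was not tested. Of the Y-linked genes, Uty was at 0.2143 CPM in library 3 and Eif2s3y at 0.03175 CPM in library 4, against 0 in the others. These values are 6 counts of Uty and 1 count of Eif2s3y. Where the other libraries are at 0, any count is flagged, so these flags carry no weight. In female knockouts library 1 stood apart for each gene concerned, low for Gm10800 (4.036 CPM against 5.677 to 5.96) and Dntt (144.5 against 182.8 to 190.3) and high for the neutrophil genes Ngp (18.2 against 0.2317 to 2.045) and Ltf (11.01 against 0.04846 to 0.761).

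The knockout effects differed between the sexes for 22 lists with camera (p adjusted over the lists), of which 0 held with an estimated correlation, so no list is shown to depend on sex by both settings. Positive medians of the male less the female effect belonged to immediate-early genes (1.197e-10), neutrophil markers (5.169e-09), myeloid priming (5.684e-08), histones (6.165e-08), lymphoid priming (3.813e-05), S phase (7.301e-05), dendritic cell markers (0.0001185), migration and Rho signalling (0.0004145), gate genes (0.0004368), T and NK cell markers (0.0004807), glycolysis (0.005831), NF-kB targets (0.006657), B cell markers (0.01498) and X-linked haematopoietic genes (0.02808). Negative medians belonged to megakaryocyte and erythroid priming (3.369e-12), stem cell identity (1.679e-06), cholesterol synthesis (1.949e-06), aged stem cells (1.081e-05), fetal and imprinted genes (0.0001286), interferon response (0.005561), G2 and M phase (0.02808) and heat shock (0.03566). Without female wild-type libraries 3 and 4, the call ended for neutrophil (0.118), dendritic cell (0.175), B cell (0.695), G2 and M phase (0.128) and heat shock (0.473) lists, and ribosomal proteins (0.0001738), oxidative phosphorylation (0.0001989), erythroid (0.001798), monocyte and macrophage (0.008434), quiescence (0.009461) and mitochondrially encoded (0.01459) lists passed. Leaving out 1 library ended the calls of glycolysis (male wild-type 3, 0.0541, or male knockout 1, 0.104), NF-kB targets (male wild-type 3, 0.0591, or male knockout 1, 0.104) and interferon response (female knockout 2, 0.191, or male knockout 3, 0.196). It ended those of the X-linked list without female wild-type 1 (0.05002), male wild-type 2 (0.0512), male knockout 1 (0.0683) or male knockout 3 (0.0653). For B cell markers these libraries were female wild-type 3 (0.393) and 4 (0.222), female knockout 2 (0.0789), male wild-type 2 (0.117) and 3 (0.0512) and male knockout 1 (0.104). For G2 and M phase they were female wild-type 3 (0.0668), female knockout 2 (0.0778) and 3 (0.0542), male wild-type 2 (0.347) and 3 (0.700) and male knockout 3 (0.184). For heat shock they were female wild-type 3 (0.186) and 4 (0.064), female knockout 1 (0.092) and 2 (0.0624), male wild-type 2 (0.153) and 3 (0.261) and male knockout 2 (0.407) and 3 (0.912).

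As many as 4311 genes differed between male and female libraries of a genotype, Xist, Pgr, Lars2 and most ribosomal protein genes among them. A GC content or gene length bias is argued against as the whole cause, since 66.62% of the wild-type calls were still made in the same direction with those trends removed. A difference in preparation or sequencing run between the sexes cannot be told apart from sex, because the labels name no run and the lowest share of ribosomal RNA in a female library was 3.931 times the highest in a male library. Sex itself, as the design names it, stays open for all genes outside the sex chromosomes. If the libraries are independent, chance can be excluded for both counts, since 1 of 35 splits, the real one, gave 4311 genes between wild types (highest other 1246), and 1 of 35 gave 4255 between knockouts (highest other 692).

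Genes called in the knockout comparisons lay close together, with Entpd4, Entpd4b, Gm16867 and Gm27177 in 1 region of chromosome 14 and 10 of the 24 female calls within 1 Mb of another, against a median of 0 and a highest of 8 in 10000 random draws. Those 10 are sets of overlapping genes, near copies or close neighbours, such as Lrmda with Gm47601 and Tmem181a with Tmem181b-ps, which can share reads. Mid1-ps1 and Gm47283, neighbours at the end of the Y chromosome, are among them. The draws took genes as separate units, so they do not measure how unusual this clustering is. Reads moved between near-identical copies inside the Entpd4 region are argued against, since its summed counts fell by a log2 fold change of -0.9517 (SE 0.0682) in males and -1.165 (SE 0.0592) in females. The region was bounded by genes called as lower in females, which favours a lower sum. Copies outside it were not summed, so reads moved there were not tested. A strain or copy-number difference between the knockout and wild-type stocks stays open, and so does an effect of the Lxn genotype, which the same libraries carry. Of those 10 genes, 100% had the same sign in males, but genes that share reads are not separate evidence. Whether chromosome within 5 Mb of Lxn carries differences cannot be told apart from chance. Of 39 genes there, 15.38% had an unadjusted p under 0.05 in females against 11.33% elsewhere (one-sided Fisher's exact p = 0.2772). In males the shares were 5.128% and 6.301% (p = 0.7139 by the same exact test). Linked chromosome outside that window was not tested. The called genes Cpa3 and Clca3a1 in females and Cpa3, Car1 and Gstm5 in males lie outside it on chromosome 3, which holds Lxn. The list of Lxn neighbours passed camera in females without female wild-type libraries 3 and 4 (0.01386).

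Marker lists of blood lineages were lower in knockouts with camera's preset correlation, neutrophil and erythroid in females and erythroid in males. None of these calls held with an estimated correlation. The erythroid genes called were not the same in the sexes. Slc4a1 fell in females (log2 fold change -4.82) and not detectably in males (-0.26, edgeR adjusted p = 0.997). Car1 fell in males (-0.98) and stood at 184.8 CPM in female wild types and 249.6 CPM in female knockouts. Neither difference between the sexes passed (edgeR adjusted p = 0.0978 for Slc4a1 and 0.0666 for Car1). Mature cells in female wild-type libraries 3 and 4 may account for the neutrophil difference, whose median went from -3.952 to 0.001743 without them (S100a8 stood at 298 and 316 CPM there), although a sort of Lineage-negative cells should remove such cells. Much of the female erythroid difference may have the same source, as its median went from -0.6169 to -0.1008, but camera still called the list (adjusted p = 0.01386). With all libraries neither erythroid call held (adjusted p = 0.158 in females and 0.140 in males with an estimated correlation). Male knockout library 1 alone is argued against as the source in males, where the erythroid median without it was -0.6232, and a lower output of these lineages in knockouts was not tested apart from the sort and stays open.

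For the number of genes called by knockout in females, 1 of 35 splits gave as many as the real 24 (highest other 9), which excludes chance only if the libraries are independent. The other splits with any calls (5 and 9 genes) kept libraries 1 and 2 and libraries 3 and 4 of each genotype together. With those pairs, whose libraries resembled each other, as units the splits are too few for a share under 0.05, here and between the sexes, and summed pairs called 6 genes. In males 10 splits are too few for a share under 0.05, and the real count was 11 and the highest other 53. That split set male wild-type library 1 with male knockout libraries 2 and 3 against the rest and points to a structure among the male libraries other than genotype. For the difference between the knockout effects, the splits decide nothing, because the real count was 0 and all 100 splits had to give at least as many (highest other 7).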

How the results depend on the processing

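The alternatives that left out female wild-type libraries 3 and 4, summed the female libraries in pairs, or used robust or GC and length offsets, and leaving out each library for the correlation between the sexes, were chosen after seeing the data. Lxn was lower in knockouts of both sexes also with DESeq2, RLE factors, limma on log2(TPM + 1), the replicate block and each library left out, and in females without wild-type libraries 3 and 4. It was not read under the other alternatives. The causes of the changes below were not tested except where named.

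Without a filter on low counts, 272 genes were called in females, 72 in males and 115 for the difference between the knockout effects, and DESeq2 called 179, 67 and 158. With limma on log2(TPM + 0.1) the female count was 15 and the male count 7, which the fit to the male groups alone also gave. With the replicate number as a block the counts were 9 in females, 4 in males, 2341 between wild types and 2772 between knockouts, but the numbers pair no libraries. Without female wild-type libraries 3 and 4 they were 101 in females, 6 for the difference and 2272 between wild types. Pairs summed gave 6 in females, 2464 between wild types and 2437 between knockouts, with fewer samples. For the difference, effective-length offsets gave 1 gene and autosomal protein-coding genes alone 3. Leaving out each library in turn gave 14 to 31 genes in females, 4 to 25 in males, 0 to 23 for the difference, 2600 to 4163 between wild types and 3211 to 3923 between knockouts.

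An estimated correlation left 2 lists in females, 0 in males, 0 for the difference, 2 between wild types and 2 between knockouts. Fry called 9 in females, 0 in males and 2 for the difference. Leaving out each library in turn gave 22 to 26, 8 to 10, 17 to 23, 10 to 14 and 13 to 17 lists with camera.

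The correlation of the knockout effects between sexes, 0.0461 over all genes, was 0.756 over genes called in either sex, which were chosen for their change, and -0.137 at a mean of at least 10 CPM. It ran from -0.0146, without male wild-type library 1, to 0.106, without male knockout library 1.

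Directions turned without female wild-type libraries 3 and 4 in females for monocyte and macrophage markers (camera adjusted p = 0.001555), B cell markers (0.9078) and ribosome biogenesis (0.04824), and for the difference in monocyte and macrophage (0.008434) and B cell markers (0.695). Thbs1, called in neither case, turned in females from -0.15 to 1.04 (adjusted p = 0.276). With limma on log2(TPM + 1), Nfe2 (adjusted p = 0.9844) and Nfkb1 (0.7954) turned between knockouts of the sexes. Leaving out single libraries turned male oxidative phosphorylation (range 7.459e-06 to 0.7707, with 0.04605 without male knockout library 3), male ribosome biogenesis (9.8e-08 to 0.731, with 0.004457 without male knockout library 2) and the heat shock difference (1.208e-17 to 0.9117, the latter without male knockout library 3).

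Depth sets the lower bounds given as folds for genes at 0 in a group. Why Mir98 had 0 counts was not tested. The cause was not tested for any change of direction.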

Other observations

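Nnt was at 60.8 to 66.2 CPM in the female wild types, 54.4 to 56.5 CPM in the male wild types and 92.6 to 109.9 CPM in the male knockouts. In female knockouts it was at 104 CPM in library 2 and at 65.7 to 78.8 CPM in the others. Hspa1a ran from 1.101 CPM in female knockout library 4 to 139.9 CPM in male knockout library 1. Col1a1, the collagen gene of stroma and bone, was at 24.5 CPM in male wild-type library 1 and at 0.180 to 6.42 CPM in the other libraries. Female libraries 1 and 2 of a genotype resembled each other, and so did 3 and 4. The mean chi-squared per gene was 4.49 to 5.75 within such pairs of wild types against 10.7 to 11.6 between them. In female knockouts the contrast was smaller, with 4.02 and 4.31 within pairs against 5.41 to 6.02 between them. No pair lay within sampling noise.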
